A study of Mus musculus with 28 samples.

How the data were processed

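The series measured total RNA, depleted of ribosomal RNA, in mouse embryonic stem cells (mESCs) and in day 5 embryoid bodies (EBs), the aggregates of differentiating cells that form after LIF is withdrawn. Per the labels' protocols, the stem cells grew on feeder fibroblasts with LIF and 2 inhibitors (2i), and feeders were depleted by plating before collection. The CJ7 line was given in 4 genotypes, each with 2 mESC and 2 EB libraries: wild type, Eed null, EloA K754M and EloA K754R, the last 2 being substitutions of 1 lysine of Elongin A. The CCE line was given as 3 EloA wild type and 3 EloA null mESC libraries and as 3 groups of 2 EB libraries. All 28 libraries were used.

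The labels of 4 CCE EB libraries contradict each other. In 1 pair, here pair A, the titles say EloA null while the names of the data columns say heterozygous, and in the other, pair B, the titles say heterozygous while the columns say null. No genotype was assigned to either pair, and both were compared with the wild type under these neutral names. The labels also do not say whether replicates are separate cultures or clones, so every p-value below measures the spread between libraries of a group, which may be technical.

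The authors deposited 1 RPKM value (reads per kilobase of exon, scaled to the library's reads) per gene and library, in 1 table for mESCs and 1 for EBs, with 37583 genes each. The submitters' processing notes name CASAVA 1.7, STAR and the mm9 mouse genome, without the role or order of each. The program that counted reads, the annotation release and the use of strand are not given in the sources used here. Reads that fall where a gene overlaps an antisense gene, or that belong to near-identical copies, therefore cannot be assigned to 1 gene, and such genes are reported as uncertain. The RPKM values carried the step of 1 read: among genes below 0.3 RPKM, 92.1% of the mESC values and 89.5% of the EB values lay within 0.02 of a whole multiple of the value that 1 read gives. Library depth was estimated from that step over 3449 genes (mESC) and 3827 genes (EB), of which 43.5% and 48.1% gave a depth within 1 percent of the one used. Depth, in units of 1000000 reads, ranged from 11.1 to 18.2 in CJ7 mESCs, from 24.3 to 46.4 in CCE mESCs, from 28.7 to 39.9 in CJ7 EBs and from 23.6 to 30.9 in CCE EBs. In CCE mESCs it went with genotype, at 24.3 to 34.7 in EloA null and 42.9 to 46.4 in wild type. The variance between replicates was 2.14 to 43.0 times the variance that read sampling alone gives at these depths. The lowest value was that of the Eed null mESC libraries. In the other CJ7 mESCs it was 13.0 (wild type), 30.1 (K754M) and 35.4 (K754R).

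Values were analysed as log2(RPKM + 0.5), which makes the fold change of a gene near or below 0.5 RPKM smaller than the ratio of its values. A gene was tested where at least 2 libraries of the fit had 0.25 RPKM or more. The test was limma-trend (limma 3.58.1 in R 4.3.3; tables and plots used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9), with 1 fit for each stage and line, moderated variances with a trend on mean expression, and Benjamini-Hochberg adjustment over the genes of 1 comparison. A gene was called higher or lower at an adjusted p below 0.05, and "rose" and "fell" are used only for such genes. The EloA null and Eed null effects in mESCs were compared by 1 more fit of all 14 mESC libraries with a contrast of the difference. Log2 changes are given ± the standard error of limma's moderated fit, and RPKM values are means of a group unless each library is given. GENCODE M21, an annotation of mm10, was used only for exon length, GC content and chromosome, joined by gene identifier (32860 of the identifiers were found). Gene names are those in the files, where 3730 genes share a name with another.

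A set of 23 gene lists was fixed before the data were examined: Elongin, PRC2 and PRC1 subunits; pluripotency; primed epiblast; Hox genes; other developmental transcription factors held by Polycomb in stem cells; cell cycle inhibitors; extraembryonic endoderm; mesoderm; blood and endothelium; neuroectoderm; trophoblast; germline; 2-cell stage; imprinted genes; p53 targets; stress response; immediate early and MAPK feedback genes; Wnt targets; retinoic acid response; proliferation; fibroblast (feeder cell) markers; replication-dependent histones; and non-coding RNAs that vary with library preparation. Each list was tested against all other genes with camera, with a preset correlation between genes of 0.01 and adjustment over the 23 lists, and again with a correlation estimated from the residuals. That second test has only the few residual degrees of freedom of its fit and can rarely pass after adjustment. Failing it is thus no evidence that a list is unchanged. Counts adjusted over the list alone are given beside counts over all genes tested. The rule for named genes, the comparisons, the tests and the other settings to try were also fixed before the data were examined. It took the targeted genes Tceb3 (the symbol of EloA in the files, ENSMUSG00000028668) and Eed (ENSMUSG00000030619), the 10 largest rises and the 10 largest falls among called genes with a mean of at least 1 RPKM in the higher group and no overlap between the groups' libraries (passing over predicted genes, clone-named Rik genes, and microRNA and nucleolar RNA names with standard prefixes), and up to 4 called members of each list. Where fewer than 5 genes were called, the 5 smallest p-values were taken. Any gene outside this rule is said to be chosen after its values were seen.

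Those other settings were pseudocounts of 0.1 and 1, no filter, a median-ratio scaling, a minimum of 2-fold, leaving out each library, 1 fit over all libraries of a stage, the replicate number as a block, and the estimated correlation. Chosen after seeing the data were the same counts without genes of chromosomes 8, 11, 14, X and Y, a fibroblast marker covariate in CJ7 mESCs, counts of genes called whichever library was left out, and a list of 20 interferon response genes. The replicate number was checked as a block by correlating, across genes, the deviations of same-numbered libraries from their group means. In CCE mESCs all 3 pairs correlated (r between 0.22 and 0.51). These values are not independent, because deviations from a group mean cancel out. In both groups library 1 also differed most from the others: its variance over sampling noise was 11.1 or more, against 4.56 and 4.58 between libraries 2 and 3. A pairing is thus possible there but was not settled, and the labels give none. The blocked value stands beside the result where it differs. Same-numbered libraries of the other fits also correlated (r between 0.01 and 0.43). With 2 numbers each pair of groups gives 1 independent value, so a pairing there was left undecided. For groups compared with the same wild type libraries, unchanged groups were simulated 20 times against those libraries (seed 11).

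The tests were first tested on simulated data made from the real means and spread. There 100 genes were changed 2-fold and 100 genes 4-fold, all taken from the better expressed genes. For the Eed null mESC comparison 23% of the 2-fold and 89% of the 4-fold genes were called, with 8 false calls. All 20198 genes tested there include the changed ones, as do the totals below. For EloA null mESCs the shares were 97% and 99% with 11 false calls among 18010, for Eed null EBs 70% and 100% with 8 among 18305, and for EB pair A 69% and 99% with 17 among 17190. A simulated raised list was called in each of these 4 comparisons, at camera p values between 6.2e-81 and 3.72e-35 with the preset correlation. Genes were simulated independently of each other. The simulation thus could not show whether p-values with the preset correlation hold for lists whose members vary together.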

Results

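RNA levels were compared in CJ7 and CCE mouse embryonic stem cells and in the day 5 embryoid bodies made from them. The title of the series joins PRC2, the complex that methylates histone H3 and needs its subunit Eed, to Elongin A, a factor that raises the rate of RNA polymerase II. The question behind each comparison was which genes differ when Eed or Elongin A is lost or when 1 lysine of Elongin A is replaced. Groups held 2 libraries each, except the CCE mESC groups with 3. Median log2 changes over all tested genes lay between -0.06 and 0.05 in every comparison, so gene changes are close to changes against the typical gene.

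Eed RNA fell in the Eed null cells at both stages. In CJ7 mESCs it was 22.3 and 22.1 RPKM in the Eed null libraries against 105 and 119 in wild type (log2 change -2.30 ± 0.25, n = 2 per group, limma adjusted p = 0.00474). In EBs it was 15.8 and 16.3 against 49.6 and 55.3 (-1.68 ± 0.10, n = 2 per group, adjusted p = 7.37e-05). Tceb3, which encodes Elongin A, fell in the EloA null mESCs, from 11.7, 11.2 and 10.7 RPKM in wild type to 8.02, 6.33 and 6.17 (-0.68 ± 0.11, n = 3 per group, adjusted p = 0.0229). At least 15.8 RPKM of Eed and 6.17 RPKM of Tceb3 thus remained in the libraries labelled null, and the tables do not say which exons were deleted. The Tceb3 call was lost without EloA null library 2 or 3 or without any 1 wild type library, at log2 changes from -0.72 to -0.62, and was kept without EloA null library 1 (-0.79). In the lines with a substitution Tceb3 did not pass the test: it was 9.22 and 8.93 RPKM in K754M mESCs (adjusted p = 0.652), 7.48 and 10.2 in K754R mESCs (0.411), 9.67 and 11.4 in K754M EBs (0.94) and 8.46 and 8.44 in K754R EBs (0.223), against 10.7 and 12.2 in wild type mESCs and 10.1 and 11.6 in wild type EBs. Eed null mESCs had 16.1 and 15.4 RPKM of Tceb3 (0.44 ± 0.18, adjusted p = 0.174) and Eed null EBs 11.2 and 14.4 (adjusted p = 0.33). In the CCE EBs Tceb3 was 7.94 and 9.09 RPKM in pair A and 7.70 and 8.64 in pair B against 9.89 and 11.4 in wild type, and neither pair passed the test (adjusted p = 0.776 and 0.297), nor did pair B against pair A (-0.06 ± 0.14, adjusted p = 0.869). Tceb3 RNA thus did not separate the pairs whose labels contradict each other. Eed fell by 0.42 ± 0.10 in K754R EBs (40.1 and 38.0 RPKM, adjusted p = 0.0478), a call that was lost without any 1 of the 4 libraries and without the filter.

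**Figure D1:**
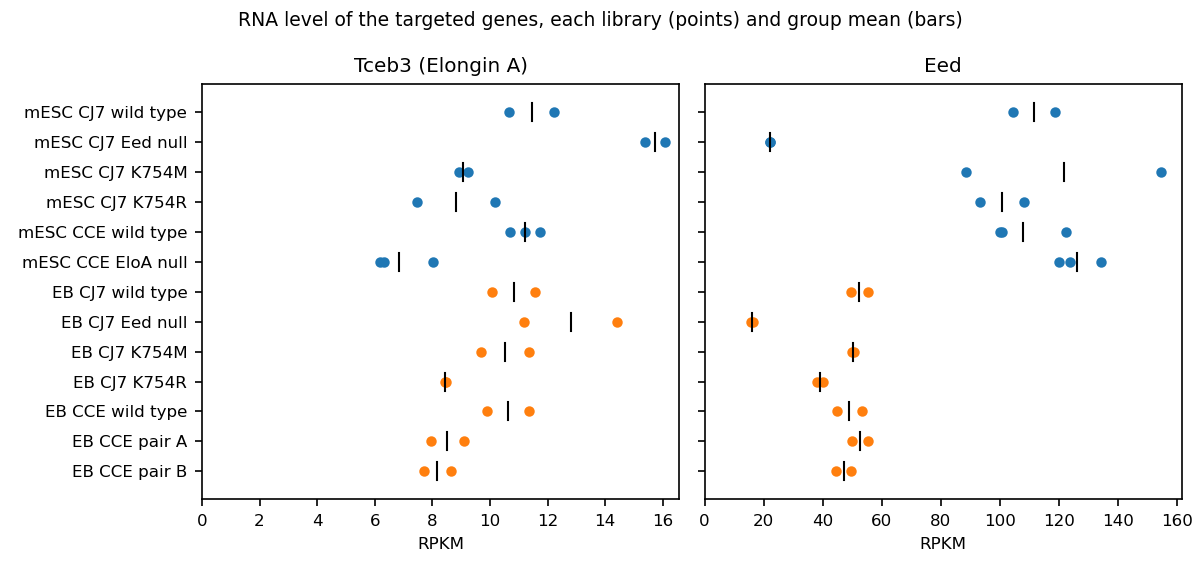
RPKM of Tceb3 (Elongin A, left) and Eed (right) on the x axis in each library (points) with the group mean (bars), for the 13 groups on the y axis. Eed lies at 22.3 RPKM or less in the 4 Eed null libraries, and Tceb3 at 8.02 or less in the 3 EloA null libraries. Tceb3 is also below 8.02 in library 1 of K754R mESCs (7.48), of pair A (7.94) and of pair B (7.70).

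**Figure D2:**
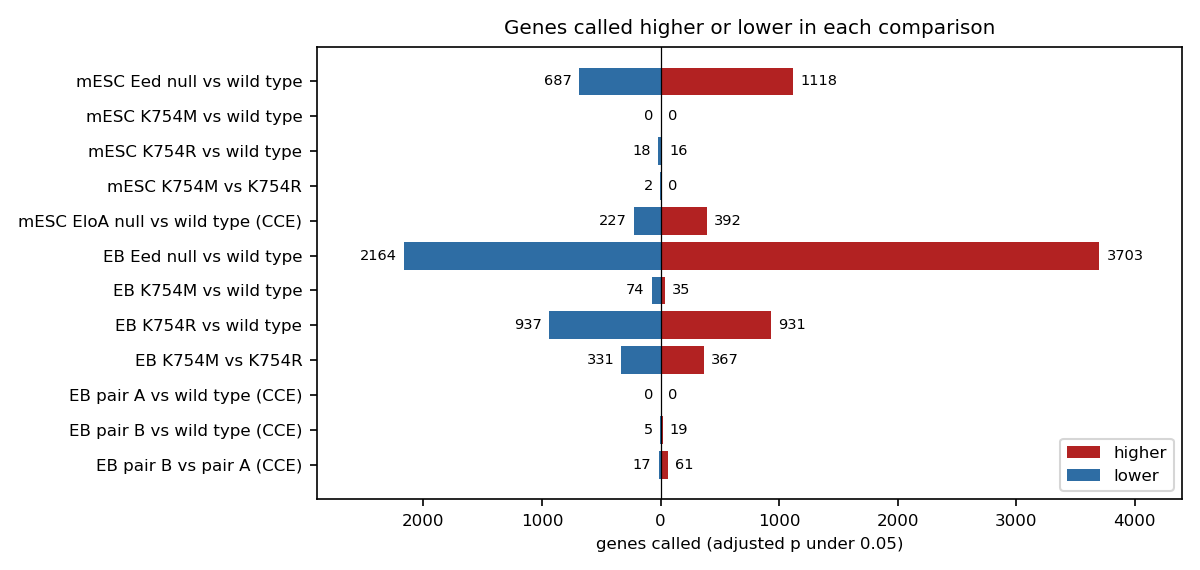
Number of genes called higher (right of 0) and lower (left of 0) at a limma adjusted p under 0.05 on the x axis, for 12 comparisons on the y axis. Eed null EBs had the most calls (3703 higher, 2164 lower), and K754M mESCs and EB pair A had 0.

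The first comparison asked which genes differ in Eed null stem cells. Many genes of the 2-cell embryo and the germline, and some developmental regulators, rose in Eed null mESCs. The transcription factor genes Olig1 and Olig2, which act in the neural lineage, were among the largest rises: Olig2 was listed at 0 in both wild type libraries and averaged 10.97 RPKM in Eed null (adjusted p = 0.000508), and Olig1 went from 0.0208 to 8.49 RPKM (log2 change 4.11 ± 0.23). Rhox6, a homeobox gene of the placenta and germline, went from 0.890 to 72.6 RPKM (5.76 ± 0.34, adjusted p = 0.000676), and the imprinted growth inhibitor Cdkn1c from 0.759 to 20.9 (4.11 ± 0.25, adjusted p = 0.000676). In all, 1118 genes rose and 687 fell of 21012 tested.

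The 2-cell stage list had the highest share of rises, 13 of 17 tested genes with no fall (14 adjusted over the list alone). Its members Zscan4c (9.90 against 0.0458 RPKM, 4.25 ± 0.27), Zscan4d (25.2 against 0.578, 4.58 ± 0.52) and Gm5662 (32.6 against 0.407, 5.30 ± 0.40) belong to families of near-identical copies, so each single value is uncertain. Of 32 germline genes 17 rose and 1 fell, among them Tex101 of spermatogenic cells (27.5 against 0.773 RPKM, 4.46 ± 0.30) and the meiotic Syce1 (81.6 against 13.02, 2.65 ± 0.25). Among developmental transcription factors held by Polycomb, 10 of 55 rose and none fell (14 adjusted over the list alone). Of the Hox genes, which pattern the body axis, 4 of 30 rose, such as Hoxa10 (3.23 against 0.577 RPKM, 1.79 ± 0.26) and Hoxd13 (2.93 against 0.720, 1.5 ± 0.27). The trophoblast list had 7 rises of 17, with the keratins Krt18 (153 against 11.5 RPKM, 3.8 ± 0.60) and Krt8 (88.0 against 8.68, 3.28 ± 0.16). In the mesoderm list 6 of 23 rose, such as the Nodal inhibitor Lefty2 (212 against 33.7 RPKM, 2.94 ± 0.69, adjusted p = 0.0491) and Gsc (12.5 against 3.16, 1.84 ± 0.23). In the extraembryonic endoderm list 5 of 27 rose and 1 fell, with the lipoprotein gene Apoa2 at 13.1 against 0.686 RPKM. Pluripotency genes mostly did not pass the test (2 rose and 1 fell of 26), though Dppa3 rose from 17.5 to 78.7 RPKM (2.26 ± 0.35) and Sox2 fell from 86.8 to 58.3 (-0.57 ± 0.11). Imprinted genes went both ways, with 7 rises and 6 falls of 36, including rises of the growth-restraining RNA H19 (166 against 11.2 RPKM, 3.83 ± 0.40) and of Sfmbt2 (66.6 against 6.25, 3.32 ± 0.25). Replication-dependent histones rose in 11 of 57 cases and fell in 1, but these genes too have near-identical copies. Camera with the preset correlation gave adjusted p = 7.8e-13 for the 2-cell, 4.81e-07 for the germline, 6.04e-07 for the developmental transcription factor, 0.000716 for the Hox, 6.81e-06 for the trophoblast, 5.86e-05 for the mesoderm, 0.00142 for the extraembryonic endoderm and 6.45e-11 for the histone list. With an estimated correlation the adjusted p values were 0.113, 0.356, 0.113, 0.356, 0.113, 0.166, 0.356 and 0.479, so none of these lists passed that way. Retinoic acid response genes (3 rises of 18), Wnt targets (4 rises of 17) and stress genes (2 rises and 3 falls of 24) also passed with the preset correlation (adjusted p = 0.000384, 0.00708 and 0.0123) and not with an estimated one (adjusted p = 0.113, 0.401 and 0.398).

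Several of the largest falls in Eed null mESCs were of small RNA genes and processed pseudogenes, whose reads can belong to near-identical copies. They included Y_RNA (8.18 against 1968 RPKM, -7.83 ± 0.39), copies of the spliceosomal U1, U4 and U5 RNAs, and the ribosomal pseudogenes Rps13-ps1 (0.0811 against 152, -8.05 ± 0.30) and Rps15a-ps8, all reported as uncertain. The same holds for the largest rise, Hist1h4m (284 against 0.0915 RPKM), and for small RNA genes of clone AL772216 on chromosome 2, of which AL772216.14 was listed at 0 in wild type and averaged 34.2 RPKM in Eed null. Postn, a fibroblast gene, fell from 43.2 to 5.42 RPKM (-2.82 ± 0.58, adjusted p = 0.0349), while the median change of the 32 fibroblast markers was 0.54 with no rise and 1 fall. Of the 1805 calls 1298 were at least 2-fold (882 higher, 416 lower), and 27.4% lay on chromosomes 8, 11, 14, X or Y against 21.2% of the genes tested. Without those chromosomes 1193 genes were called (853 higher, 340 lower), and with all mESC libraries in 1 fit 5211. The calls fell in number to 179 and 185 without Eed null library 1 or 2 and to 323 and 417 without wild type library 1 or 2. Whichever library was left out, 147 genes were called (81 higher, 66 lower), with Eed, Rhox6, Olig1, Cdkn1c, H19, Krt8, Tex101, Syce1, Zscan4c and Gm5662 among them. By list these were 4 of the 13 risen 2-cell genes, 2 of 17 germline genes, 1 of 10 developmental transcription factors (Olig1 and not Olig2), 1 of 7 trophoblast genes, 2 of 11 histones, and 4 of the 7 rises and 1 of the 6 falls of imprinted genes. None of the calls in the Hox, mesoderm, extraembryonic endoderm, pluripotency, neuroectoderm and stress lists was among them.

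Eed null embryoid bodies were compared with wild type EBs to ask which genes differ during differentiation. Most of the pluripotency, germline, extraembryonic endoderm and Hox genes tested were higher in the Eed null EBs, and most mesoderm genes were lower. Zfp42, a marker of naive stem cells, was 234 RPKM against 7.94 (log2 change 4.79 ± 0.28), the orphan receptor gene Nr0b1 33.4 against 0.209 (5.58 ± 0.21) and the DNA methylation cofactor Dnmt3l 81.8 against 1.503 (5.36 ± 0.16). Afp and Apob, products of visceral endoderm, were 87.3 against 1.46 RPKM (5.50 ± 0.34) and 71.9 against 1.62 (5.09 ± 0.16). Mesp1, the regulator of early cardiac mesoderm, fell from 46.5 to 1.32 RPKM (-4.64 ± 0.31, adjusted p = 9.17e-05). In all, 3703 genes rose and 2164 fell of 19300 tested.

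Of 26 pluripotency genes 19 rose and none fell (21 adjusted over the list alone), such as Esrrb (19.9 against 0.330 RPKM) and Dppa3 (65.1 against 2.52, 4.44 ± 0.18), and all 19 were called whichever library was left out. Germline genes rose in 25 of 31 cases with no fall, among them Tex19.1 (89.0 against 2.28 RPKM, 5.00 ± 0.20) and the transposon-silencing factor Mael (11.6 against 0.377, 3.81 ± 0.25). The extraembryonic endoderm list had 26 rises and 3 falls of 34. Hox genes rose in 22 of 30 cases and fell in 2, led by Hoxd13 (3.82 against 0.0824 RPKM, 2.87 ± 0.20) and Hoxd8 (4.74 against 0.305, 2.71 ± 0.22), and 6 of those rises were called whichever library was left out. In the mesoderm list 17 of 27 fell, such as the receptor Kdr (2.87 against 21.5 RPKM, -2.72 ± 0.21) and Hand1 (1.53 against 11.9, -2.62 ± 0.23), while 3 rose, with Lefty2 at 97.8 against 5.64 RPKM. Aplnr, a receptor of mesoderm cells, and Cfc1, a cofactor of Nodal, also fell (1.32 against 19.8 RPKM and 6.01 against 66.6). Trophoblast genes rose in 10 of 18 cases and fell in 1, including the keratin Krt7 (18.2 against 1.22 RPKM, 3.44 ± 0.19). Developmental transcription factors held by Polycomb went both ways, with 22 rises such as Olig2 and 19 falls of 55. Cell cycle inhibitors had 5 rises and 1 fall of 7, Cdkn1c showing the largest (145 against 2.18 RPKM, 5.76 ± 0.19, adjusted p = 1.53e-05). Of 39 imprinted genes 15 rose and 12 fell, the maternal RNA Rian falling from 217 to 32.8 RPKM (-2.71 ± 0.11). Among Elongin and Polycomb subunits 7 of 29 rose and 3 fell, Eed with them, and the PRC1 member Cbx7 rose from 5.32 to 24.3 RPKM (2.09 ± 0.27).

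Camera with the preset correlation gave adjusted p = 3.6e-11 for the pluripotency, 1.19e-13 for the germline, 6.3e-09 for the extraembryonic endoderm, 7.88e-08 for the Hox, 1.07e-06 for the mesoderm, 0.000143 for the trophoblast and 0.0299 for the cell cycle inhibitor list. The adjusted p with an estimated correlation was 0.0997, 0.121, 0.133, 0.121, 0.0997, 0.0997 and 0.214, so no list passed that way. The other lists in Eed null EBs had 11 rises and 2 falls of 23 stress genes (adjusted p = 0.00704, and adjusted p = 0.254 with an estimated correlation), with the chaperone Hspb1 at 109 against 17.6 RPKM. There were 11 rises of 22 p53 targets (camera adjusted p = 0.0104, and adjusted p = 0.359 with that estimate) and 4 rises of 6 genes of the 2-cell stage (camera adjusted p = 0.0145, and adjusted p = 0.319 with that estimate). Of 56 histone genes 5 rose and 20 fell (camera adjusted p = 0.00044, and adjusted p = 0.752 with that estimate). The rest did not pass: developmental transcription factors (0.834), imprinted genes (0.834), the Elongin and Polycomb subunits (0.757), and neuroectoderm with 9 rises and 1 fall of 18 (0.056). Nor did blood and endothelium with 5 and 4 of 18 (0.919), primed epiblast with 5 and 2 of 14 (0.589), or immediate early and MAPK feedback genes with 5 and 3 of 21 (0.589). The same was so of Wnt targets with 5 and 5 of 18 (0.374), and retinoic acid response genes with 6 and 3 of 18 (0.232). It was so too of proliferation with 5 and 2 of 26 (0.589), fibroblast markers with 8 and 5 of 28 (0.65), and non-coding RNAs with 1 and 4 of 12 (0.137). Sign differed between summaries in some: developmental transcription factors had a median of 0.12 and a mean of 0.11 with a test direction of lower, and immediate early genes a median of -0.25, a mean of 0.01 and a test direction of lower.

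Calls of at least 2-fold numbered 2663 (1871 higher, 792 lower), and 4506 genes were called off chromosomes 8, 11, 14, X and Y (3117 higher, 1389 lower). Whichever library was left out, 2604 genes were called (1678 higher, 926 lower), including all 10 largest rises and 9 of the 10 largest falls; the embryonic globin Hbb-bh1 (17.5 and 1.63 RPKM in the 2 wild type libraries) was not among them. By list these were 11 of the 25 germline rises, 21 of 26 extraembryonic endoderm rises, 5 of 10 trophoblast rises, 14 of 17 mesoderm falls, and 5 of the 22 rises but 16 of the 19 falls of developmental transcription factors, where falls then outnumber rises. They were also 10 of the 15 rises and 10 of the 12 falls of imprinted genes, 6 of 11 stress, 3 of 11 p53 target, 1 of 9 neuroectoderm and 0 of 4 2-cell rises, and 10 of 20 histone falls. The largest falls also held the pseudogenes Rps13-ps1, Rps15a-ps8, Rps15a-ps6, Rps15a-ps7 and Rps15a-ps5, whose reads may belong to copies.

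**Figure D3:**
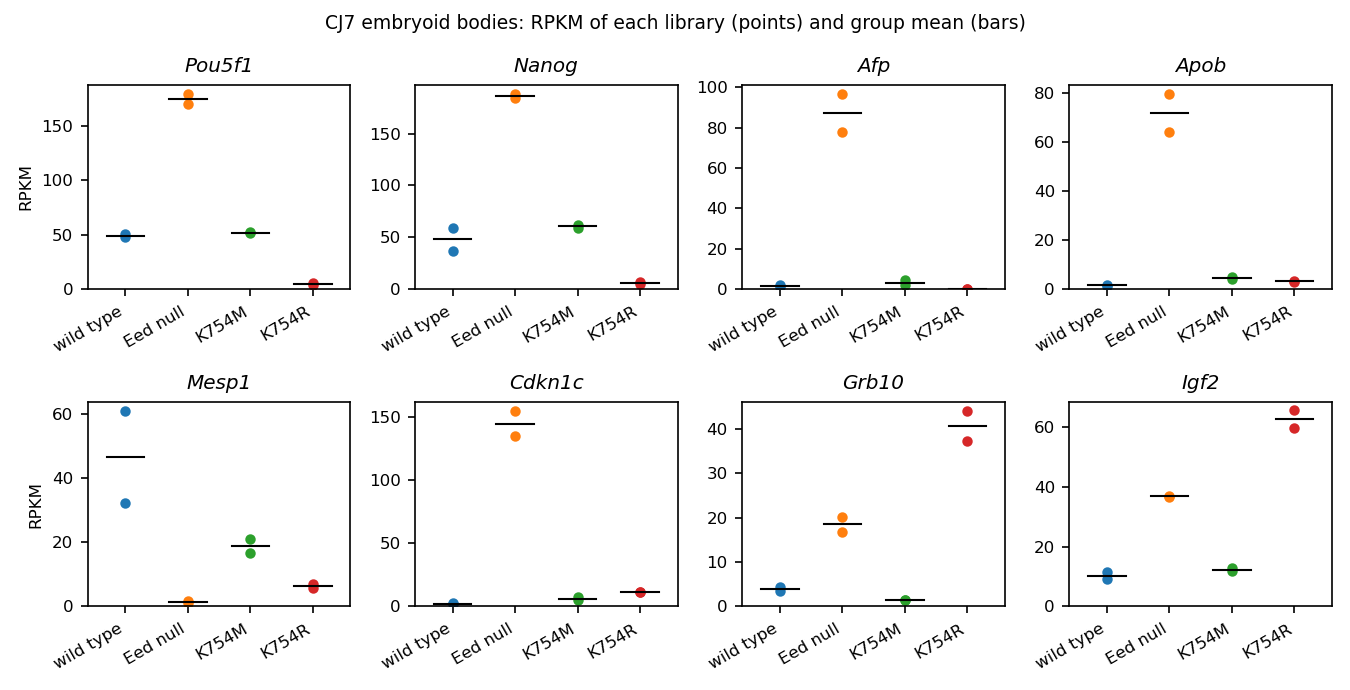
RPKM (y axis) of 8 genes in each CJ7 EB library (points) with the group mean (bars), for wild type, Eed null, K754M and K754R. Mesp1 averages 1.32 in Eed null and 46.5 in wild type, and Grb10 40.7 in K754R and 3.94 in wild type.

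**Figure D4:**
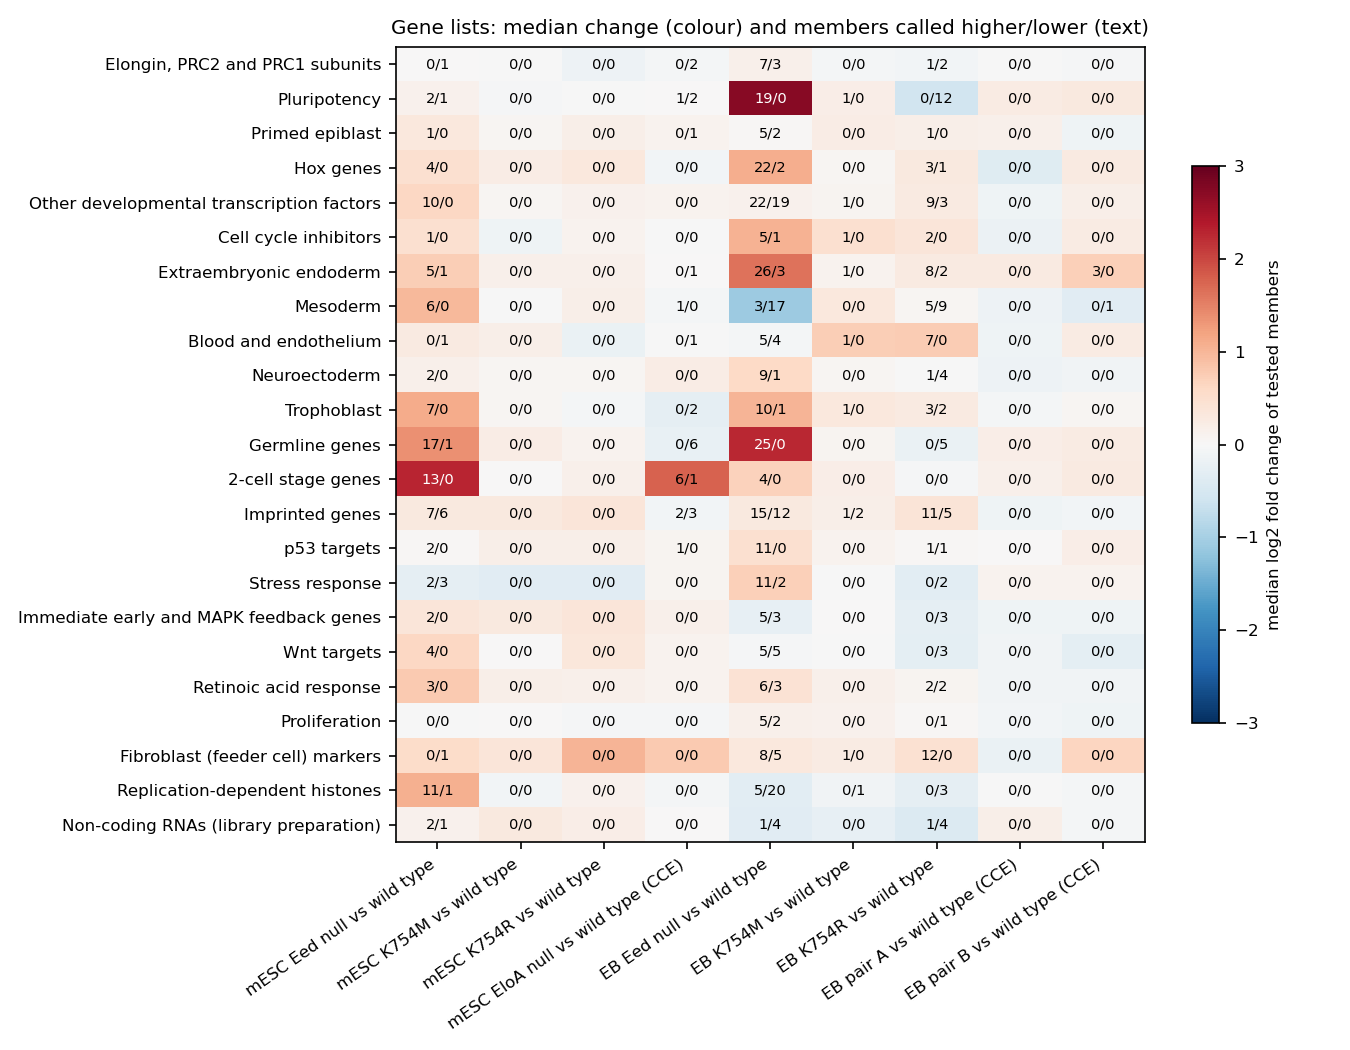
Median log2 change of the tested members (colour) of 23 gene lists (y axis) in 9 comparisons (x axis), with the members called higher and lower as text. In Eed null EBs 19 pluripotency genes were higher and 0 lower, and 3 mesoderm genes were higher and 17 lower.

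Over the 276 list tests of all 12 comparisons, 89 passed camera with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.0997. With so few residual degrees of freedom per fit, failing with an estimated correlation does not count against a list. Those 89 were 11 in Eed null mESCs, 3 in K754M mESCs, 4 in K754R mESCs, 2 between the substitutions in mESCs and 4 in EloA null mESCs. In EBs they were 11 in Eed null, 11 in K754M, 14 in K754R, 9 between the substitutions, 10 in pair A, 6 in pair B and 4 between the pairs. The lists described here are those with the most called genes or the smallest p.

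Eed null stem cells and EBs were set side by side to ask which changes the stages shared. Rhox6, Cdkn1c, Olig2 and Sfmbt2 rose at both stages and Eed fell at both. In the mesoderm list 6 of 23 genes rose in mESCs and 17 of 27 fell in EBs, and this difference between stages was not tested. Across genes the log2 changes correlated at r = 0.31 (genes are not independent replicates), 446 genes were higher at both stages against 178 for independent lists of these sizes, 194 were lower at both against 67.5, and 154 went opposite ways.

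Stem cells with the K754M or K754R substitution were compared with wild type to ask whether the lysine matters for RNA levels. No gene passed the test in K754M mESCs (0 of 21012 with limma, 2103 at an unadjusted p under 0.05). The smallest p-values there were of AL772216.14, 5S_rRNA, AL731857.1, Gm364 (7.84 against 34.96 RPKM) and 1700013H16Rik (97.3 against 36.3), all at adjusted p = 0.0649. In K754R mESCs 16 genes rose and 18 fell. The cation channel gene Trpm1 rose from 0.392 to 5.59 RPKM (log2 change 2.82 ± 0.31, adjusted p = 0.0422), the X-linked Magea10 from 0.281 to 3.90 (2.50 ± 0.24), Rragb, a GTPase gene of amino acid sensing, from 2.71 to 12.9 (2.05 ± 0.23) and the collagen gene Col18a1 from 8.56 to 32.7 (1.87 ± 0.18). The lipase gene Liph fell from 22.0 to 4.33 RPKM (-2.21 ± 0.22, adjusted p = 0.0381), Pipox from 25.5 to 5.64, the transaminase gene Gpt2 from 61.8 to 15.0 (-2.0 ± 0.16), and the cytokine genes Ccl25 and Inhbe by 1.96 and 1.87 on the log2 scale. Between the 2 substitutions only Ube1y1, a Y-linked gene, and Gm364 passed the test, both lower in K754M (0.4501 against 12.2 RPKM, -3.72 ± 0.28, and 7.84 against 63.7, -2.95 ± 0.20, both adjusted p = 0.0438), and the Y-linked Zfy1 and Kdm5d came next (adjusted p = 0.0681 and 0.0698). No list held a called gene in K754M or K754R mESCs. By camera with the preset correlation, Hox genes lay above other genes in both lines (28 of 30 members above 0 in K754R, adjusted p = 0.000159, and 24 of 30 in K754M, 0.023), but not with an estimated correlation (adjusted p = 0.633 and 0.694). Fibroblast markers lay higher in K754R mESCs (31 of 32 above 0, median 1.02, adjusted p = 6.32e-05, and adjusted p = 0.633 with an estimated correlation), mostly in library 2: their mean log2 level was 3.08 and 4.56 in K754R libraries 1 and 2 against 2.82 and 2.93 in wild type. With that level as a covariate, chosen after seeing the data, 1 gene was called in K754R and none of the 34 calls was left. Non-coding RNAs lay higher in K754M (13 of 13 above 0, camera adjusted p = 0.00164, and adjusted p = 0.604 with that estimate), and stress genes lower in both (median -0.33 in K754M and -0.34 in K754R, adjusted p = 0.00577 and 0.00151, and adjusted p = 0.604 and 0.633 with that estimate). Without any 1 of the 4 libraries of a comparison 0 genes were called in K754R mESCs and 0 between the substitutions. Off chromosomes 8, 11, 14, X and Y, 12 genes were called in K754R (8 higher, 4 lower) and 0 between the substitutions. With all mESC libraries in 1 fit the calls were far more: 955 in K754M (322 higher, 633 lower), 1747 in K754R and 841 between the substitutions.

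The EBs with K754R had 931 genes higher and 937 lower than wild type, of 19300 tested. Some pluripotency genes fell, some genes of endothelium and fibroblasts rose, and mesoderm and imprinted genes went both ways. Pou5f1 and Nanog, core factors of pluripotent cells, fell from 49.0 to 4.53 RPKM (log2 change -3.33 ± 0.19, n = 2 per group, adjusted p = 0.00063) and from 47.9 to 5.89 (-2.88 ± 0.21, adjusted p = 0.00136). T and Msgn1, of nascent mesoderm, fell from 63.5 to 10.5 (-2.54 ± 0.16) and from 4.76 to 0.0922 (-3.13 ± 0.32). The imprinted growth genes Grb10 and Igf2 rose from 3.94 to 40.7 (3.22 ± 0.16, adjusted p = 0.000468) and from 10.2 to 62.5 (2.57 ± 0.13).

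Xist, the RNA that silences an X chromosome in female cells, was the largest rise in K754R EBs (31.6 against 0.257 RPKM, 5.41 ± 0.24, adjusted p = 0.000468). Of the pluripotency list 12 of 26 genes fell and none rose, with Tdgf1 at 23.8 against 154 RPKM (-2.66 ± 0.15). In the mesoderm list 9 of 27 fell, Mesp1 among them (6.47 against 46.5, -2.69 ± 0.31), and 5 rose, Hand2 among them. Blood and endothelium genes rose in 7 of 18 cases with no fall, such as the receptor Tek (4.58 against 0.582 RPKM, 2.23 ± 0.18) and Fli1 (6.84 against 1.51, 1.93 ± 0.26). Of 28 fibroblast markers 12 rose and none fell, including Postn (9.58 against 0.339, 3.56 ± 0.35), Acta2 (26.0 against 2.99, 2.91 ± 0.33) and Twist2 (10.2 against 1.69, 2.32 ± 0.23). Imprinted genes had 11 rises and 5 falls of 39, Cdkn1c rising from 2.18 to 11.3 RPKM. Extraembryonic endoderm genes had 8 rises and 2 falls of 34, the Hox list 3 and 1 of 30, other developmental transcription factors 9 and 3 of 55, germline genes 0 and 5 of 31, and Wnt targets 0 and 3 of 18. The interferon-induced GTPase genes Gbp1 and Gbp2 were among the largest falls (0.364 against 18.2 RPKM, -4.42 ± 0.21, and 0.567 against 19.7, -4.23 ± 0.23). Suz12, a PRC2 subunit, fell from 38.0 to 18.04 RPKM (-1.05 ± 0.23, adjusted p = 0.0345). It lies on chromosome 11, whose median log2 change in this comparison was -0.38.

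By camera the pluripotency (adjusted p = 3.06e-06), fibroblast (8e-05), blood and endothelium (0.00039) and imprinted lists (0.00629) passed with the preset correlation, each at adjusted p = 0.383 with an estimated correlation. The germline (0.00156), Hox (0.0015) and Wnt lists (0.00299) also passed at first and had an estimated-correlation adjusted p of 0.383, the developmental transcription factor list (0.0015) one of 0.561, the extraembryonic endoderm list (0.0104) one of 0.422, and the histone list (8.36e-05, 3 falls of 56) one of 0.609. For the mesoderm list (0.576) the median was 0.06, the mean -0.24 and the test direction lower. Of the 1868 calls 824 were at least 2-fold (349 higher, 475 lower), and 1174 genes were called off chromosomes 8, 11, 14, X and Y (628 higher, 546 lower). With the replicate number as a block 2950 genes were called. Calls numbered 177 and 214 without K754R library 1 or 2, 1249 without wild type library 1 and 264 without wild type library 2, and 1199 without the filter. In K754R 135 genes (52 higher, 83 lower) were called whichever library was left out, among them Xist, Grb10, Igf2, Postn, Acta2, Tek, Pou5f1, Nanog, Tdgf1, T, Msgn1, Mesp1, Gbp1 and Gbp2, but not Suz12. By list these were 4 of the 12 pluripotency falls, 4 of 9 mesoderm falls and none of the 5 mesoderm rises, 2 of 7 endothelium rises, 4 of 12 fibroblast rises, 5 of the 11 imprinted rises and none of the 5 falls, 1 of 5 germline falls and 2 of 3 Wnt target falls. Of the developmental transcription factors 1 rise and 1 fall were left, and none of the extraembryonic endoderm or Hox calls.

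The EBs with K754M had 35 genes higher and 74 lower than wild type. The largest falls included genes that interferon induces: Psmb8 of the immunoproteasome fell from 5.34 to 0.0851 RPKM (log2 change -3.31 ± 0.20, n = 2 per group, adjusted p = 0.00351), Gbp1 from 18.2 to 1.71 (-3.07 ± 0.21), Gbp2 from 19.7 to 2.04 (-2.99 ± 0.23) and Parp9 from 8.13 to 1.23. Eif2s3y, a Y-linked gene, fell from 24.9 to 5.68 RPKM (-2.04 ± 0.10, adjusted p = 0.00236). Acta2, the smooth muscle actin, rose from 2.99 to 17.6 (2.38 ± 0.33, adjusted p = 0.0427), Ctla2a from 2.30 to 8.65 (1.72 ± 0.17) and the Nodal inhibitor Lefty1 from 2.52 to 8.33 (1.60 ± 0.24). Pou5f1 and Nanog did not pass the test. Of the fixed lists, 1 of 26 pluripotency genes rose (Dppa4, 6 adjusted over the list alone), 1 of 18 blood and endothelium genes (9 rises and 1 fall over the list alone), 1 of 28 fibroblast markers (Acta2, 10 over the list alone), and 1 of 39 imprinted genes rose while 2 fell, Grb10 (1.39 against 3.94 RPKM) being 1 of them. Camera gave adjusted p = 0.00505 for the pluripotency, 7.18e-05 for the blood and endothelium and 0.000104 for the fibroblast list, and adjusted p = 0.411 for each with an estimated correlation. At least 2-fold were 25 higher and 58 lower calls, and off chromosomes 8, 11, 14, X and Y 31 genes were called (9 higher, 22 lower). With the replicate number as a block 230 genes were called, and with all EB libraries in 1 fit 434. The counts were 0 without K754M library 1 or 2 or wild type library 2, 17 without wild type library 1, and 58 without the filter, and no gene was called whichever library was left out.

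The substitutions were also compared with each other in EBs, where 367 genes were higher and 331 lower in K754M than in K754R. Pluripotency genes were higher in K754M: Pou5f1 was 51.9 against 4.53 RPKM (log2 change 3.42 ± 0.19, n = 2 per group, adjusted p = 0.00101), Nanog 60.4 against 5.89 (3.26 ± 0.21), Dppa5a 145 against 13.7 (3.45 ± 0.34), and 14 of 26 list members were called higher and none lower. Mesoderm genes were higher in 9 of 27 cases and lower in 3, with T at 49.0 against 10.5 (2.17 ± 0.16). Germline genes were higher in 7 of 31 cases. Xist (0.305 against 31.6 RPKM, -5.31 ± 0.24), Grb10 (1.39 against 40.7, -4.44 ± 0.16) and Igf2 (12.2 against 62.5, -2.31 ± 0.13) were lower. Camera with the preset correlation gave adjusted p = 1.7e-12 for pluripotency, 1.3e-07 for germline and 0.00667 for mesoderm genes, and adjusted p = 0.235, 0.429 and 0.3 with an estimated correlation. At least 2-fold were 249 higher and 164 lower calls, and 479 genes were called off chromosomes 8, 11, 14, X and Y (268 higher, 211 lower). With the replicate number as a block 1099 genes were called, and with all EB libraries in 1 fit 1358. Calls numbered 21 and 37 without K754M library 1 or 2, 64 and 30 without K754R library 1 or 2, and 425 without the filter. Of the 698, 19 genes were called whichever library was left out (15 higher, 4 lower), with Pou5f1, Nanog, Dppa4, L1td1, Tdgf1, T, Xist, Grb10 and Igf2 among them. These were 4 of the 14 pluripotency genes, 1 of the 9 higher mesoderm genes and none of the 7 germline genes.

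The EloA null mESCs of the CCE line were compared with CCE wild type to ask what loss of Elongin A does in stem cells. There 392 genes rose and 227 fell of 18460 tested, mostly by less than 2-fold. Every EloA null library was shallower than every wild type library, and what depth adds to these calls was not tested. Some genes of the 2-cell embryo rose, among them Zfp352 (3.41 against 0.159 RPKM, log2 change 2.43 ± 0.38, n = 3 per group, adjusted p = 0.0241), Tdpoz3 (2.54 against 0.217, 1.94 ± 0.38) and the near-identical Zscan4e and Zscan4f. Pdlim3, a muscle cytoskeleton gene, rose from 0.153 to 2.10 (2.00 ± 0.22, adjusted p = 0.00774). The X-linked Xlr4a (2.37 against 9.86 RPKM, -1.86 ± 0.14), Xlr3c, Xlr5a, Xlr4b and Xlr3a fell, but these are near-identical copies and uncertain. The lipase gene Liph fell from 4.72 to 1.27 (-1.57 ± 0.12, adjusted p = 0.00339) and the betaine pathway genes Bhmt2 and Bhmt from 4.70 to 1.24 and from 2.48 to 0.528.

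In the 2-cell stage list 6 of 16 genes rose, and 1 fell (Pramel7, 1.60 against 6.35 RPKM, -1.75 ± 0.33); adjusted over the list alone these were 10 and 2. Germline genes fell in 6 of 30 cases with no rise, including Tuba3a (32.8 against 77.0 RPKM, -1.22 ± 0.05, with a near-identical copy), the stem cell and germ cell gene Tex19.1 (58.0 against 95.1, -0.70 ± 0.11) and Fkbp6 (19.3 against 28.3, -0.54 ± 0.06). Of 29 Elongin and Polycomb subunits 2 fell, Tceb3 and Suz12 (34.3 against 43.7 RPKM, -0.34 ± 0.04). Suz12 lies on chromosome 11, whose median log2 change in this comparison was -0.11. Pluripotency genes had 1 rise, Lin28a (33.6 against 22.3, 0.58 ± 0.09), and 2 falls, Klf4 (31.6 against 41.9, -0.40 ± 0.05) and Fbxo15. The keratins Krt18 (3.68 against 7.74 RPKM, -0.98 ± 0.16) and Krt8 (11.03 against 15.5, -0.48 ± 0.07) were the 2 falls of 10 trophoblast genes, opposite in direction to Eed null mESCs. None of 23 Hox genes or 25 other developmental transcription factors passed. Of 34 imprinted genes 2 rose and 3 fell. Fibroblast markers lay higher in EloA null (32 of 32 above 0, median 0.78, none called), a fact to set beside the rises above. Camera with the preset correlation gave adjusted p = 2.06e-05 for the 2-cell, 2.84e-05 for the germline, 2.84e-05 for the fibroblast and 0.0473 for the p53 target list, and adjusted p = 0.638, 0.638, 0.881 and 0.638 with an estimated correlation.

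Chromosomes 8, 11, 14, X and Y held 49.9% of these calls and 20.7% of the genes tested. Without any genes of those chromosomes, 163 genes were called (72 higher, 91 lower). On chromosome 14, 193 of the 403 better expressed genes rose. That count took only genes with a minimum mean log2 level of 1, the limit used for chromosome medians. At least 2-fold were 64 higher and 54 lower calls. With the replicate number as a block 1232 genes rose and 1056 fell, and the immediate early and MAPK feedback list (median 0.14) then passed camera as well (adjusted p = 0.0294 with the preset correlation). Under the block 1 Hox gene, Hoxb13 (-0.97), and 2 other developmental transcription factors, Nkx6-2 (0.73) and Gbx2 (0.39), also passed. Calls numbered 370, 327 and 211 without EloA null library 1, 2 or 3 and 640, 158 and 161 without wild type library 1, 2 or 3, and 296 in the fit of all mESC libraries. In EloA null 130 genes were called whichever library was left out (99 higher, 31 lower), among them Pdlim3, Xlr4a, Xlr3c, Liph and Tuba3a. Tuba3a was the only 1 of the 6 germline falls, and none of the 6 risen 2-cell genes held, nor did any called gene of the pluripotency or trophoblast lists or of the Elongin and Polycomb subunits, Tceb3 and Suz12 among these. The fits with a library left out were made without the block and so did not use any pairing of the libraries.

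The EloA null and Eed null effects in mESCs were also set against each other. The difference between them was tested in 1 fit of all 14 mESC libraries, where 1210 genes had a higher and 1747 a lower change in EloA null than in Eed null, of 21780 tested. Across genes the 2 sets of log2 changes correlated at r = 0.18. EloA null correlated with K754M and K754R mESCs at r = 0.13 and 0.22. Higher in both EloA null and Eed null were 47 genes against 18.99 for independent lists of these sizes. Lower in both were 25 against 7.85, and 38 went opposite ways. Off chromosomes 8, 11, 14, X and Y these were 29 against 7.91 and 11 against 3.55. The 2-cell stage list rose in both lines by the preset-correlation test, 13 of 17 genes in Eed null and 6 of 16 in EloA null, and its call was lost in both with an estimated correlation (adjusted p = 0.113 and 0.638).

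The CCE embryoid bodies were compared with wild type to ask the same in differentiated cells, under the contradicting labels given above. In pair A no gene passed the test (0 of 17735 with limma, 1166 at an unadjusted p under 0.05). Its smallest p-values were of AC132957.1, AC154683.1, the TGF-beta mediator Smad3 (5.65 against 12.2 RPKM, adjusted p = 0.663), Cldn7 (17.98 against 9.09) and Col1a1 (2.64 against 7.20). Hox genes lay lower in pair A by camera (1 of 31 above 0, median -0.37, adjusted p = 2.69e-09, and adjusted p = 0.493 with an estimated correlation). In pair B 19 genes rose and 5 fell. Among the rises were the endocytic receptor of visceral endoderm Lrp2 (14.9 against 2.40 RPKM, log2 change 2.38 ± 0.20, n = 2 per group, adjusted p = 0.0427), its partner Amn (7.98 against 0.764, 2.72 ± 0.23), the water channel Aqp8 (10.2 against 0.938, 2.90 ± 0.26), the protease Ctsh (19.7 against 3.62, 2.30 ± 0.16, adjusted p = 0.04) and the folate receptor Folr1 (5.97 against 0.893). Myl7, an atrial myosin gene, fell from 7.34 to 1.54 (-1.94 ± 0.19). Of 31 extraembryonic endoderm genes 3 rose, or 16 with 1 fall adjusted over the list alone, and of 28 mesoderm genes 1 fell, or 7 with 1 rise over the list alone. Camera gave adjusted p = 1.11e-10 and 0.000232, and adjusted p = 0.333 for both with an estimated correlation. Calls in pair B numbered 0 without pair B library 1 or 2 or wild type library 1, 1 without wild type library 2 and 1 without the filter. At least 2-fold were 18 higher and 5 lower, and off chromosomes 8, 11, 14, X and Y 11 genes were called (8 higher, 3 lower). With the replicate number as a block 703 genes were called, and with all EB libraries in 1 fit 591.

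Between the 2 pairs 61 genes were higher and 17 lower in pair B. Tgfbi, a matrix protein induced by TGF-beta, was 15.4 against 1.69 RPKM (log2 change 2.91 ± 0.34), Amn 7.98 against 0.935, Aqp8 10.2 against 1.42 and the basement membrane laminin Lama1 18.96 against 4.27 (2.02 ± 0.21), all at adjusted p = 0.0487. Cer1, a secreted Nodal inhibitor, was 0.525 against 7.30 (-2.92 ± 0.24) and Myl7 1.54 against 12.6 (-2.67 ± 0.19). Of 31 extraembryonic endoderm genes 6 were higher and none lower, and of 25 fibroblast markers 2 were higher (17 and 1 lower adjusted over the list alone). Camera gave adjusted p = 2.61e-05 and 4.6e-08, and adjusted p = 0.681 and 0.421 with an estimated correlation. The number of calls moved both ways with the settings: 794 genes were called with all EB libraries in 1 fit, 93 with a pseudocount of 1, but 1 gene (0 higher, 1 lower) was called with median-ratio scaling, 1 with a pseudocount of 0.1, 32 without the filter, 1 off chromosomes 8, 11, 14, X and Y, 1 without pair A library 1 or 2, and 0 without pair B library 1 or 2. At least 2-fold were 48 higher and 13 lower calls. The largest number, 1462, came with the replicate number as a block.

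Groups compared with the same 2 wild type libraries share the chance values of those libraries, so their log2 changes correlate with no effect at all. Across genes, K754M and K754R EBs correlated at r = 0.57 against 0.50 in simulated unchanged groups, with a covariance of 0.117 against 0.0305. They shared 23 genes higher (1.69 for independent lists) and 55 lower (3.59), such as Acta2, Ctla2a, Gbp1, Gbp2 and Psmb8, while 3 genes went opposite ways, among them Grb10. Eed null and K754R EBs correlated at r = 0.098 against 0.50 (covariance 0.0425 against 0.0305), sharing 258 genes higher (179 for independent lists) and 334 lower (105), with 334 opposite, Pou5f1 and Nanog among those that fell in K754R. Off the same chromosomes they shared 216 higher (144) and 188 lower (56.4). Eed null and K754M EBs gave r = 0.32 against 0.50 (covariance 0.102 against 0.0304), and the CCE pairs 0.32 against 0.50 (0.0390 against 0.0335). In mESCs the values were 0.32 for Eed null and K754M (covariance 0.123 against 0.0694), 0.45 for Eed null and K754R (0.200 against 0.0691) and 0.56 for the substitutions (0.143 against 0.0682), each against a simulated r of 0.50. Part of any excess, in correlation or in shared genes, may come from the shared controls, which were not split between the groups. Shared genes were not counted in the simulated groups. With no shared libraries, pair B correlated with Eed null, K754M and K754R EBs at r = 0.25, 0.25 and 0.36. Pair A correlated with them at -0.04, -0.24 and -0.24. Pair B shared 15 genes higher with Eed null EBs against 3.08 for independent lists, Aqp8 among them. EloA null mESCs correlated with pair B at 0.19 and with pair A at -0.04, and mESCs with EBs of the same line at 0.14 for K754M and 0.17 for K754R.

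Whole chromosomes differed between the lines. Genes of chromosome 11 lay lower than wild type in all 3 CJ7 mutants, with medians of -0.37, -0.41 and -0.44 in Eed null, K754M and K754R mESCs and of -0.33, -0.40 and -0.38 in the EBs. In EloA null mESCs the chromosome 11 median was -0.11, with 75.1% of its genes lower. Genes of chromosome 8 lay lower in Eed null (-0.35 in mESCs and -0.37 in EBs). K754R mESCs also had lower medians on chromosomes 4 (-0.17, 63.7% lower), 12 (-0.175, 70.7% lower) and 8 (-0.14, 66.9% lower), with -0.02, 0.05 and -0.06 in the EBs; chromosomes 4 and 12 were not among those left out of the counts. Chromosome 14 genes lay higher in EloA null mESCs (0.45, 92.1% of 403 genes above 0), in pair B (0.45) and in K754R mESCs and EBs (0.32 and 0.41), but not in pair A (0.00) or K754M mESCs and EBs (0.04 and 0.05). X-linked genes lay higher in K754R (0.30 in mESCs, 0.22 in EBs). Y-linked genes lay lower in K754M (-2.17 over 6 genes in mESCs and -1.38 over 3 in EBs) and in EloA null mESCs (-1.33 over 3 genes). Y-linked genes in K754R were at 0.56 in mESCs (6 genes) and -0.59 in EBs (3 genes), and over 3 genes pair A was at 0.57 and pair B at -0.14. Named genes that lie where such a shift was measured in their comparison include Grb10, Igfbp3, Pipox and Suz12 (11), Gpt2 and Zfp42 (8), Trav19 and Gch1 (14), and Magea10 (X). The changes of Grb10 and Igfbp3 in K754R EBs are far larger than that shift.

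**Figure D5:**
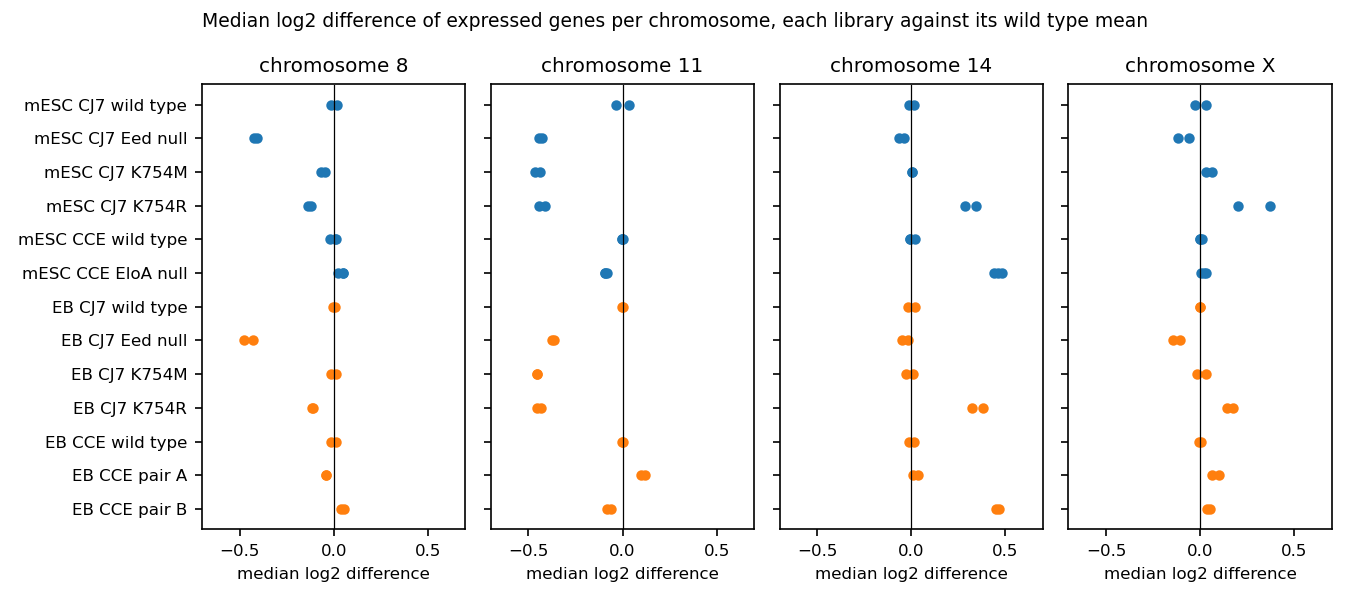
Median log2 difference (x axis) of the genes of chromosomes 8, 11, 14 and X in each library (points) against the wild type mean of its line and stage, for 13 groups (y axis). The 3 EloA null mESC libraries lie between 0.44 and 0.48 on chromosome 14.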

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

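The tests of other splits of the EloA null libraries, of chromosome 11 copies and of both Xist explanations were chosen after the result was seen; the tests of chromosome 11 dose in the CJ7 wild type, of the title of pair B and of GC content and length were not. Whether a mutation itself caused these chromosome and Xist patterns was not tested, since each mutation was present in 1 line.

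Genes of chromosome 11 were lower in all 3 mutant CJ7 lines, at both stages. GC content and transcript length were argued against, because after a fit on both the chromosome median nearest to 0 over the 6 comparisons was still -0.42. A higher dose of chromosome 11 in the CJ7 wild type cells may be the source: the CJ7 wild type lay above the CCE wild type by a median of 0.321 in mESCs and 0.330 in EBs, while the 3 mutants lay between -0.15 and -0.05. For a gain or loss of copies in any of the lines, of which that dose would be a case, the test could not decide. The lowest share of lower genes over the 6 comparisons was 73.1%, in Eed null EBs. It fell between the bounds of 75 and 60 percent, which were set after the data were seen. Calls of chromosome 11 genes that moved by about as much as the chromosome median in a comparison with CJ7 wild type cannot be told apart from a difference in copies, which does not hold for Grb10 in K754R EBs (3.22 against a median of -0.38).

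Genes of chromosome 14 were higher in EloA null mESCs and in EB pair B, but not in pair A. GC content and length were argued against, with a lower chromosome median of 0.43 after a fit on both. That pair B came from the EloA null line and carries a wrong title stays open: of 129 genes called in EloA null mESCs on other chromosomes, 85 (65.9%) moved the same way between pair B and pair A, just past the bound of 65 percent set before, against 53.5% for pair A and 66.7% for pair B each against wild type. With no bounds set, medians in EloA null mESCs, pair B and pair A were -1.33, -0.14 and 0.57 over 3 Y-linked genes and -0.11, -0.08 and 0.09 on chromosome 11, so pair B lay nearer than pair A on both but without most of the fall in Y. What keeps it open, for reasons not set as bounds before, is that K754R, another line, also had higher chromosome 14 genes (0.32 and 0.41), that a heterozygous line could share these directions, and that Tceb3 did not separate the pairs (8.17 against 8.52 RPKM), so no genotype was assigned.

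Xist was 31.6 RPKM in K754R EBs against 0.257 in wild type. RNA of female feeder fibroblasts was argued against, since the lowest ratio of Xist to the fibroblast collagen Col1a2 in K754R EBs was 410.4 times the highest ratio in any mESC library. A further X chromosome in part of the K754R cells may be the source: the lower of the 2 X chromosome medians in K754R mESC libraries was 0.20 above wild type, and the other was 0.37. Whether the substitution itself raised Xist was not tested, as there was 1 K754R line.

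The test of the difference between EloA null and Eed null effects in mESCs singled out 2957 genes, across cell lines that also differ in background. That between K754M and K754R singled out 2 genes in mESCs and 698 in EBs, and that between pair B and pair A 78 genes. The 619 genes called in EloA null mESCs were set against other splits of the 6 libraries: 1 of the 10 splits, the real one, gave as many, the highest of the others called 0, and 10 splits are too few for a share under 0.05.

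Other lists were singled out because every library of a line moved one way in mESCs and the opposite way in EBs against wild type, by the mean log2 level of the list. These differences were not tested, and 8 such cases were seen in 69 pairs of list and line, where 3.83 arise by chance if the pairs are independent. They are not, since the lines share their wild type libraries, so the 2 numbers cannot be compared closely. Mesoderm genes were at 0.89 in Eed null mESCs and -0.998 in EBs, and at 0.19 and -0.24 in K754R. Neuroectoderm genes were at 0.10 and -0.23 in K754R, stress genes at -0.51 and 0.64 in Eed null, and Wnt targets at 0.49 and -0.50 in K754R. Immediate early and MAPK feedback genes were at 0.28 and -0.0575 in K754M and at 0.40 and -0.37 in K754R, and non-coding RNAs that vary with library preparation were at 0.32 and -0.21 in K754M. Most of the K754R rise in mESCs came from library 2: the levels were 2.24 and 2.98 against 2.19 and 2.23 in wild type for immediate early and MAPK feedback genes, 0.91 and 1.62 against 0.73 and 0.82 for Wnt targets, and 0.45 and 0.70 against 0.42 and 0.36 for mesoderm genes. That library also had the raised level of fibroblast markers given above.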

How the results depend on the processing

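Over the planned and added alternatives no called gene, list or correlation of effects changed sign. The larger side of a count did change: from 392 higher and 227 lower to 72 and 91 off the named chromosomes in EloA null mESCs, and from 367 and 331 between the substitutions in EBs to 319 and 343 with a pseudocount of 1, 205 and 220 without the filter and 665 and 693 with all libraries in 1 fit. The near-even counts of K754R (931 and 937 in EBs, 16 and 18 in mESCs) also changed sides, for example to 1466 and 1323 with all EB libraries in 1 fit and to 8 and 4 in mESCs off those chromosomes. In Eed null mESCs 88 rose and 91 fell without Eed null library 1, and 92 and 93 without library 2. Values of single genes kept their side of the threshold in 6746 cases, lost the call in 1316 (988 of them with a library left out) and gained it in 161. List results kept their call in 1002 cases, lost it in 92 (89 with the estimated correlation, 1 with a pseudocount of 1, 2 with the block) and gained it in 10. The share of higher genes in the lowest of 4 expression bins moved without the filter in 10 of 12 comparisons, for Eed null from 60.8% to 49.0% in mESCs and from 60.5% to 68.8% in EBs, where that bin then held more genes near 0. Lists were not run with libraries left out. Where a library was left out of a group of 2, the lone library was assumed to vary like the other groups. The fibroblast covariate and the counts off chromosomes 8, 11, 14, X and Y were chosen after seeing the data. Counts of at least 2-fold fall by construction. Off chromosomes the p-values were kept and adjusted again over the remaining genes: 28 of 78 calls between the pairs and 309 of 619 in EloA null mESCs lay on those chromosomes, and the rest of each loss came from that adjustment. For every other value here the cause was not tested. With the means and replicate spread of the CJ7 mESCs, 23% of simulated 2-fold changes in better expressed genes were called. Counts there thus leave out many changes of that size.

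Leaving out 1 library, the calls ranged from 179 to 417 for Eed null mESCs (1805 with all), 0 to 0 for K754M mESCs, 0 to 0 for K754R mESCs (34), 0 to 0 between the substitutions in mESCs (2), 158 to 640 for EloA null mESCs (619), 3921 to 4647 for Eed null EBs (5867), 0 to 17 for K754M EBs (109), 177 to 1249 for K754R EBs (1868), 21 to 64 between the substitutions in EBs (698), 0 to 0 for pair A, 0 to 1 for pair B (24), 0 to 1 for pair B against pair A (78) and 1190 to 2468 for the difference of effects (2957). Of that last one, calls were 1190 and 1272 without Eed null library 1 or 2, 1929 without CJ7 wild type library 1, and 1911 and 1943 without CCE wild type library 2 or 3.

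With all libraries of a stage in 1 fit the calls were 5211 for Eed null, 955 for K754M, 1747 for K754R, 841 between the substitutions and 296 for EloA null in mESCs, and 434 for K754M, 1358 between the substitutions, 591 for pair B and 794 for pair B against pair A in EBs. Without the filter they were 14 for K754R and 0 between the substitutions in mESCs, 58 for K754M, 1199 for K754R, 425 between the substitutions, 1 for pair B and 32 for pair B against pair A. With a pseudocount of 0.1, 1 gene was called in K754M mESCs and 1 between the pairs, with a pseudocount of 1, 0 between the substitutions in mESCs, and with median-ratio scaling 1 between the pairs. The fibroblast covariate gave 3077 for Eed null, 1 for K754M, 1 for K754R and 0 between the substitutions in mESCs. Off chromosomes 8, 11, 14, X and Y there were 1193, 12, 0 and 163 calls for Eed null, K754R, the substitutions and EloA null in mESCs, and 31, 1174, 11 and 1 for K754M, K754R, pair B and the pairs in EBs. At least 2-fold were 118 (EloA null), 2663 (Eed null EBs), 824 (K754R EBs), 413 (substitutions, EBs) and 1580 (difference of effects).

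The replicate number as a block gave 2288 calls in EloA null mESCs, where a pairing is possible but was not settled. Of the results named in the report the block changed no other call there than those given beside it. Elsewhere same-numbered libraries deviated together at r between 0.03 and 0.35 in CJ7 mESCs, 0.01 and 0.23 in CJ7 EBs and 0.18 and 0.43 in CCE EBs, with only 2 numbers, and the block gave 2 calls for K754R and 0 between the substitutions in mESCs, and 230 for K754M, 2950 for K754R, 1099 between the substitutions, 703 for pair B and 1462 between the pairs in EBs.

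Correlations across genes moved with a pseudocount of 0.1 and of 1 to -0.02955 and -0.05567 for Eed null EBs and pair A, -0.1552 and -0.2832 for K754M and pair A, -0.17 and -0.2715 for K754R and pair A, 0.283 and 0.321 for Eed null mESCs and EBs, and 0.123 and 0.217 for EloA null mESCs and pair B. With 0.1 they moved to 0.209 for K754M and pair B, 0.286 for K754R and pair B and 0.126 for K754R mESCs and EBs. Off the named chromosomes they were 0.296 for Eed null, 0.0711 for K754M and 0.128 for K754R between stages, and 0.149 for EloA null mESCs and pair B.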

Other observations

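Chosen after the results were seen were the interferon list and the counts by class of small RNA given here. Genes induced by interferon were lower in both EloA substitution lines as EBs. Of 20 such genes, 8 fell in K754M EBs, among them Gbp1, Gbp2, Gbp3, Isg15 and Psmb8 (median log2 change -0.90), and 12 fell in K754R EBs, with the restriction factors Bst2 and Ifitm3 and the regulator Irf1 besides (median -1.78). None rose in either. In Eed null EBs 13 rose, and Gbp1 fell (median 0.96), and in CCE pairs A and B none passed. Since the list was drawn up after these falls were seen, its camera p values of 2.26e-16 and 2.68e-13 (p = 0.0201 and 0.029 with an estimated correlation) in K754M and K754R are no independent evidence. Gbp1 was 15.7 and 20.6 RPKM in the CJ7 wild type EBs, the libraries that both lines were compared with.

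Small RNA genes were counted by class in the Eed null lines, without a test of the classes; of all genes 1118 rose and 687 fell of 21012 in mESCs, and 3703 and 2164 of 19300 in EBs. Of 1095 small nuclear, nucleolar and Y RNA genes tested in mESCs, 136 fell and 21 rose (median -0.45), and of 1013 in EBs 161 fell and 40 rose. Of microRNA genes 79 of 366 rose and 5 fell in mESCs (median 0.69), and in EBs 98 of 423 rose and 53 fell. In K754R mESCs, where 34 genes were called in all, 5 microRNA genes rose and none fell (median 0.58). Many of these genes have near-identical copies. Tested genes were put in 4 bins of equal size by mean expression. In the lowest bin 307 rose and 28 fell in Eed null mESCs and 1096 rose and 176 fell in Eed null EBs; in the highest bin 243 rose and 358 fell in mESCs and 701 and 796 in EBs. Without the filter the lowest bin, with more genes near 0, had 65 rises and 7 falls in mESCs and 437 and 52 in EBs.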
